A study of Rattus norvegicus with 91 samples.

How the data were processed

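The authors deposited 1 signal per probe set and array, in intensity units on the linear scale, for 2 Affymetrix array designs with 8799 and 15923 probe sets. The scanner software and the way probes were combined are not given in the sources used here. The arrays of the short course shared a 2% trimmed mean of 800 and those of the long course one of 150. The exception, 6 h replicate 3 of the short course, stood at 150 and was multiplied to the common value. Otherwise the deposited scaling was kept, since 97.87% and 100% of the arrays shared a scale. The array titled 96 h replicate 1 in the long course is described as 72 hours, and its title was used. The array titled 48 h replicate 1 in the long course carries the description wording of the short course and was kept where its title puts it. Values of 1081 and 946 pairs of arrays were compared within each course and 0 pairs were identical.

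Signals were taken as log2(signal + 32). Affymetrix control probe sets, 59 and 57, were left out, as were probe sets below the 30th percentile of mean signal. Group means were fitted with limma 3.58.1 in R 4.3.3 over all arrays of a course, so that groups of 2 to 4 arrays share an estimate of spread, with a moderated variance that follows the signal level. Windows are unweighted means of their times. P-values were adjusted by Benjamini and Hochberg over the probe sets tested, and an adjusted p under 0.05 counts as past the threshold. In simulations with 200 changed probe sets the code recovered 70% to 92% at a log2 change of 1 and 16% to 50% at 0.5. False calls were 3% to 7.6%, and real arrays may give more.

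A probe set was named only if it had 1 gene symbol, which held for 7006 probe sets of the short and 12783 of the long course. The 10 higher and 10 lower genes with the largest log2 change past the threshold were named at 4-8 h of the short course and at 6-18 h and 72-168 h of the long course, and 5 and 5 in the other windows. Tat and Nr3c1 were read everywhere, and up to 4 members of each list described, those with the largest change in its direction. Each gene stands for its brightest probe set.

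Altogether 29 gene lists, 20 of pathways and 9 of cell type markers, were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Lists with fewer than 5 measured genes were not tested. List p-values were adjusted over 140 tests in the short and 81 in the long course, and apart for the comparisons of late with earlier windows. "Adjusted over the list alone" counts members with the adjustment made within the list. Windows, lists, tests, thresholds and the rule for naming genes were set before the data were examined. Other scalings, added constants, filters, array weights, blocks and left-out arrays were tried, and those chosen after seeing the arrays were the spike-in batch, parted at a log2 level of 9, the arrays with a mean correlation under 0.9 and the array left on its own scale. The adjustment of the tests of short-course genes in the long course, over 6 tests, was added after their p-values were seen.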

Results

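Liver RNA from Wistar rats labelled with 50 mg/kg methylprednisolone, a synthetic glucocorticoid that acts through the glucocorticoid receptor, was measured on Affymetrix expression arrays of 2 designs. The table called the short course here holds 47 arrays, with 4 controls labelled time 0 and 16 times from 0.25 to 72 h. Each time has 3 arrays, except 2, 5, 12, 30 and 72 h with 2 each. The long course holds 44 arrays of the other design, with 4 controls and 4 arrays at each of 10 times from 6 to 168 h. After removal of control probe sets and of the dimmest probe sets, 6118 probe sets of 3582 named genes were tested in the short course and 11106 probe sets of 8066 genes in the long course. The labels state no route, dosing schedule, vehicle or time of day. They do not say whether replicate arrays are separate animals, so every error and p-value measures only the spread between these arrays, which may be technical. The number of arrays limits the precision. The courses were scaled apart, and no level is compared between them.

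The stated aim was to follow many liver transcripts over time after the drug. Times were therefore averaged in windows fixed in advance, each compared with the controls of its own course, and the last window was also compared with the window of the main response. The windows hold 9 arrays at 0.25-0.75 h, 5 at 1-2 h, 17 at 4-8 h, 5 at 12-18 h and 7 at 30-72 h in the short course. In the long course they hold 16 arrays at 6-18 h, 12 at 24-48 h and 12 at 72-168 h. Changes below are log2 differences ± standard error, and a bracket ends with the number of arrays in the window that lay on that side of the reference mean.

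Tyrosine aminotransferase (Tat), the classical glucocorticoid-induced enzyme of the liver, and the glucocorticoid receptor gene Nr3c1 were read first. In the short course Tat rose at 4-8 h by 0.79 ± 0.23 (adjusted p = 0.0108, 17 of 17 arrays). Nr3c1 fell by 0.56 ± 0.19 (adjusted p = 0.0274, 17 of 17). Tat signal was 6463 ± 3157 in the controls (SD, n = 4). It was 12700 ± 1759 at 5 h (n = 2) and 3628 ± 563.7 at 18 h (n = 3). Some 4-8 h arrays lay below the top control, 9713. Nr3c1 signal was 260.5 ± 25.48 in the controls and 138.9 ± 15.2 at 7 h (n = 3). In the long course Tat rose at 6-18 h by 1.41 ± 0.27 (adjusted p = 0.000424, 16 of 16 arrays), at 24-48 h by 1.03 ± 0.27 (adjusted p = 0.0168, 11 of 12) and at 72-168 h by 0.91 ± 0.27 (adjusted p = 0.024, 12 of 12). Long-course Tat signal was 887 ± 422.9 in the controls and 3697 ± 1428 at 6 h, and Nr3c1 signal was 413.5 ± 112 in the controls and 236.8 ± 24.71 at 18 h (SD, n = 4 each). Long-course Nr3c1 did not pass in any window, with changes of -0.45 (adjusted p = 0.163, 15 of 16 arrays), -0.10 (adjusted p = 0.88) and -0.47 (adjusted p = 0.139, 12 of 12). In the other short-course windows the Tat values were 0.16, 0.63, -0.59 and -0.14 and the Nr3c1 values -0.30, -0.55, -0.29 and -0.03, none past the threshold (lowest adjusted p = 0.118).

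At single times Tat passed at 5.5 h of the short course (0.96 ± 0.32, adjusted p = 0.044). In the long course it passed at 6 h (2.08 ± 0.34, adjusted p = 6.59e-05), 10 h (1.71, adjusted p = 0.000901), 18 h (1.23, adjusted p = 0.0224), 36 h (1.41, adjusted p = 0.00748), 48 h (1.32, adjusted p = 0.0173) and 168 h (1.13, adjusted p = 0.0302). Nr3c1 passed at no single time. These calls leaned on single control arrays. In the short course the 4-8 h call of Tat ended without control 1 (adjusted p = 0.12) or control 4 (adjusted p = 0.0852), and Tat passed at 1-2 h without control 2 (adjusted p = 0.0395). The call of Nr3c1 ended without control 1 (adjusted p = 0.0877), control 3 (adjusted p = 0.0609) or control 4 (adjusted p = 0.0743). Tat in the long course ended at 24-48 h without control 2 (adjusted p = 0.184) or control 3 (adjusted p = 0.0784) and at 72-168 h without control 2 (adjusted p = 0.209) or control 3 (adjusted p = 0.104), while Nr3c1 passed at 72-168 h without control 4 (adjusted p = 0.0399).

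**Figure D1:**
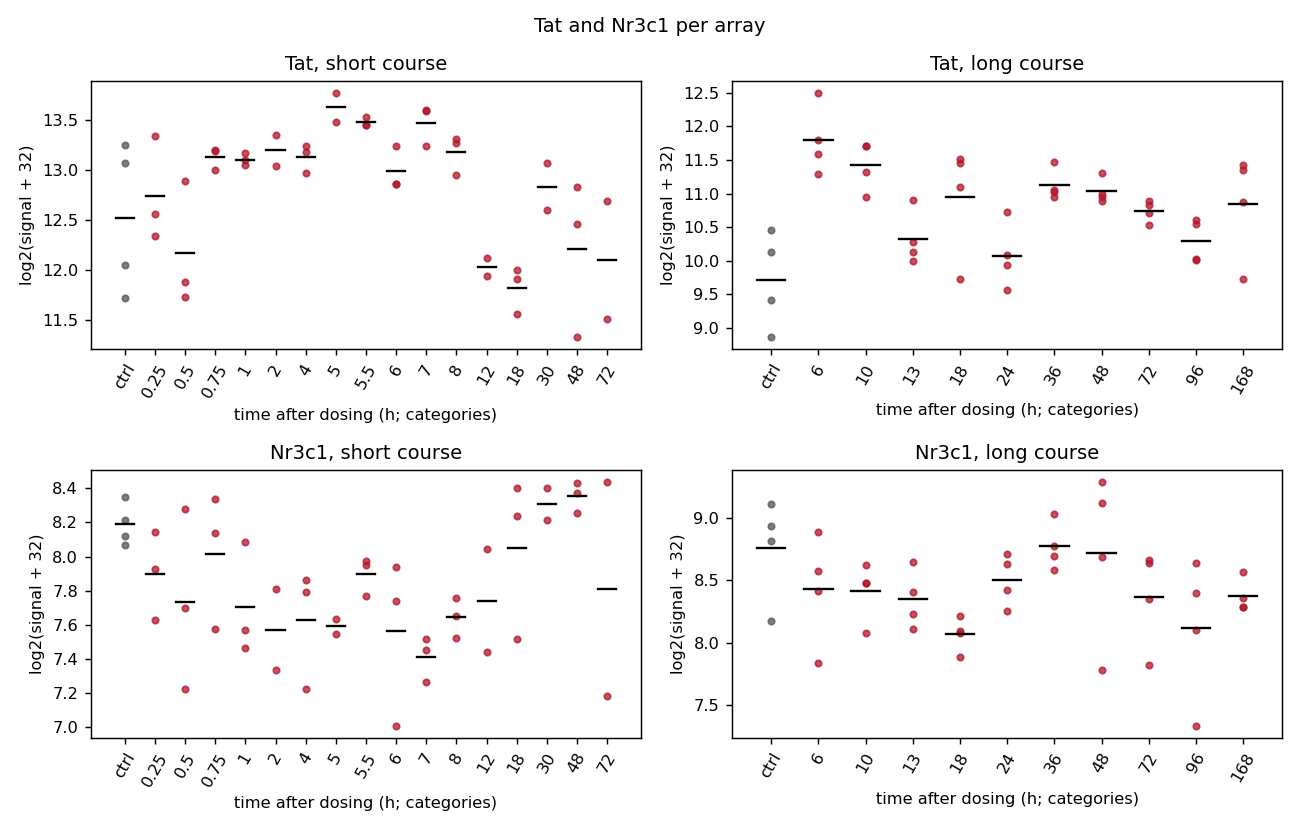
Signal of Tat and Nr3c1 on each array of both courses, as log2(signal + 32), against labelled time in hours. Controls are grey and bars mark group means. Tat lay above the control mean in 17 of 17 short-course arrays at 4-8 h and 16 of 16 long-course arrays at 6-18 h. In both courses some lay below a control.

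At some time 2040 of 6118 short-course and 2637 of 11106 long-course probe sets changed (limma moderated F test). Among the former the largest departure from control fell most often at 2 h (415 probe sets, 2 arrays) and then at 4 h (250). In the long course it fell most often at 10 h (397) and 168 h (360). Such counts favour noisy groups and do not time the response. Against control 1642 probe sets passed at 4-8 h of the short course and 6 at 30-72 h, and in the long course 1207 passed at 72-168 h. Among the long-course arrays, 15 carried high and 29 low signals of the spiked-in bacterial control transcripts, a batch that held every array numbered replicate 4. With that batch as a block 2955 long-course probe sets changed at some time, with the low arrays alone 1914, and with the high arrays alone, mostly 1 per group, 7.

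**Figure D2:**
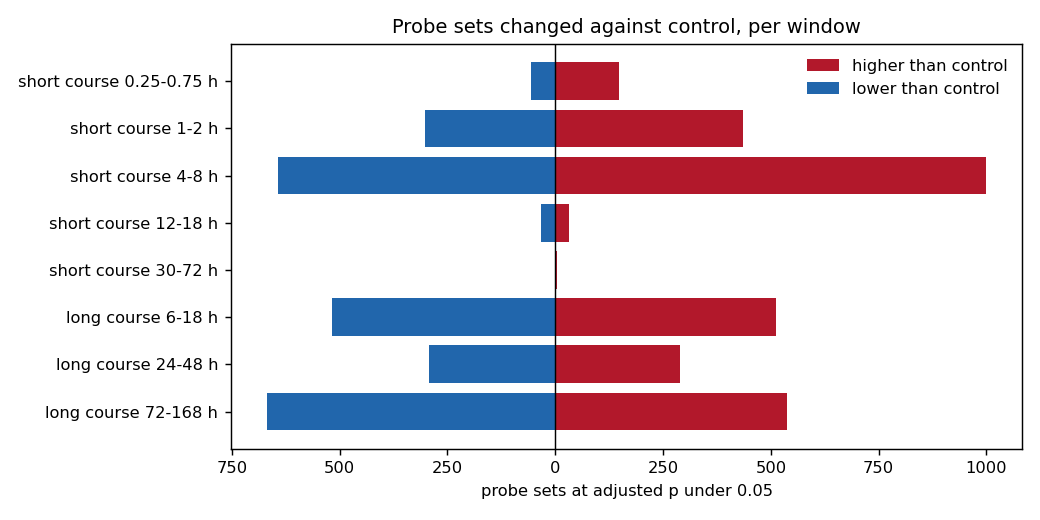
Number of probe sets with an adjusted p under 0.05 that were higher (red) or lower (blue) than control in each time window of the short and the long course. The short course had 1000 higher and 642 lower at 4-8 h and 5 higher and 1 lower at 30-72 h, and the long course had 538 higher and 669 lower at 72-168 h.

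Within the first hour, at 0.25-0.75 h of the short course, the largest rises included chemokines and a cytokine, which attract and activate leukocytes. Ccl3 was 16 times and Il1b 8.12 times its control level, and 205 probe sets passed, 148 higher and 57 lower. The largest rises were Ccl3 (probe set U22414_at, 4.00 ± 0.62, adjusted p = 0.000193, 8 of 9), Cxcl2 (3.12 ± 0.75, adjusted p = 0.0181, 8 of 9) and Il1b (3.02 ± 0.44, adjusted p = 8.45e-05, 8 of 9). The other 2 were the calcium-binding protein of neutrophils and macrophages S100a8 (2.94 ± 0.70, adjusted p = 0.0172, 9 of 9) and the interferon-induced chemokine Cxcl10 (2.90 ± 0.68, adjusted p = 0.0155, 9 of 9). Falls were largest for 2 plasma proteins, the kininogen Kng2 (probe set K02814_at, -5.90 ± 1.72, adjusted p = 0.049, 9 of 9) and the heme carrier Hpx (-5.42 ± 1.34, adjusted p = 0.0217, 9 of 9). Both probe sets read erratically in this course. Among the 4 controls Hpx signal ran from 30.04 to 24660 and Kng2 from 2951 to 27840, whereas on the long-course arrays Hpx ran from 6734 to 12280 in the controls and from 5793 to 12480 at 6 h. The urinary protein gene Obp3 (-3.11 ± 0.57, adjusted p = 0.0019, 9 of 9), the pyruvate dehydrogenase kinase Pdk4 (-1.91 ± 0.50, adjusted p = 0.0293, 8 of 9) and Amacr (-1.91 ± 0.54, adjusted p = 0.0408, 8 of 9), a racemase of bile acid synthesis, also fell. Calls ended without control 3 for Cxcl2, S100a8, Kng2, Hpx, Pdk4 and Amacr (adjusted p 0.0722 to 0.239), without control 4 for Cxcl2, S100a8, Cxcl10, Kng2, Hpx, Pdk4 and Amacr (adjusted p 0.0682 to 0.168) and without 0.25 h replicate 2 or 0.75 h replicate 1 for Kng2, Pdk4 and Amacr (adjusted p 0.0505 to 0.0986). They also ended without 0.25 h replicate 3, 0.5 h replicate 3 or control 1 for Kng2 (adjusted p 0.0535 to 0.0874), without 0.5 h replicate 2 or 0.75 h replicate 3 for Kng2 and Amacr (adjusted p 0.0622 to 0.0789) and without 0.75 h replicate 2 for Kng2 and Pdk4 (adjusted p 0.0503 to 0.0522). Calls ended too without control 2 for Pdk4 (adjusted p = 0.0837).

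Inflammatory mediators and interferon targets moved up by a median of 0.63 (camera adjusted p = 1.05e-08, 0.468 with an estimated correlation), and 10 rose and 21 did not pass of 31 (15 rose adjusted over the list alone). Among 20 immediate-early genes, 3 rose and 17 did not pass (10 rose adjusted over the list alone), and the median was 0.67 (camera adjusted p = 0.000624, 0.501 with an estimated correlation). Myc (2.17 ± 0.57, 9 of 9) and Zfp36 (2.09 ± 0.27, 9 of 9) rose. Zfp36 encodes an mRNA-decay protein. Of the 15 glucocorticoid-induced genes, 4 rose and 11 did not pass (9 rose adjusted over the list alone), with a median of 0.86 (camera adjusted p = 1.84e-05, 0.468 with an estimated correlation). Nfkbia (2.72 ± 0.36, 9 of 9) and Cebpd (2.57 ± 0.62, 9 of 9) rose. Neutrophil markers moved up by a median of 0.94, where 2 of 6 rose (camera adjusted p = 0.0326, 0.496 with an estimated correlation). The 3' to 5' signal ratio of GAPDH, a sign of RNA breakdown, was 0.143 ± 0.139 (SD, log2) in the 4 controls and -0.028 ± 0.242 in the 14 arrays from 0.25 to 2 h. Leaving out 1 array ended calls without control 3 or control 4 for Cebpd and Myc (adjusted p 0.0771 to 0.135) and without 0.25 h replicate 2 for Myc (adjusted p = 0.0676).

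Hepatocyte secretory proteins moved down by a median of -0.52 (camera adjusted p = 2.42e-09, 0.468 with an estimated correlation), and 2 fell and 15 did not pass of 17 (14 fell adjusted over the list alone). Plg (-0.53 ± 0.15, 9 of 9) and Apoh (-0.46 ± 0.12, 9 of 9) fell. Fatty acid oxidation and ketogenesis genes moved down by a median of -0.18, where 3 of 21 fell (camera adjusted p = 0.00152, 0.535 with an estimated correlation). Calls were lost without 0.25 h replicate 2, control 3 or control 4 for Plg and Apoh (adjusted p 0.0512 to 0.264) and without 0.5 h replicate 1, 0.75 h replicate 2 or 0.75 h replicate 3 for Plg (adjusted p 0.0585 to 0.0713).

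At 0.25-0.75 h, 4 lists passed as higher, 6 as lower and 18 did not pass, and 0 passed with an estimated correlation. The plot of all lists shows those not described. The count of 205 moved with single arrays: it was 88 without 0.25 h replicate 2, 367 without 0.25 h replicate 3, 329 without control 1, 567 without control 2, 47 without control 3 and 41 without control 4. The split between higher and lower also depended on scaling, at 123 and 82 after quantile normalization and 84 and 78 after centring each array on its median. Ended list calls are named here and below for the lists described. Quantile normalization ended the call of the hepatocyte secretory proteins (median -0.06, adjusted p = 0.292), and the median of fatty acid oxidation was -0.29 after median centring. Without the arrays of low correlation with the rest, the neutrophil markers did not pass (adjusted p = 0.0887).

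At 1-2 h the largest rises again included chemokines. Cxcl10 was 17.6 times and Ccl3 15.4 times the control level, and 739 probe sets passed, 436 higher and 303 lower. The largest rises were Cxcl10 (probe set U17035_s_at, 4.14 ± 0.77, adjusted p = 0.000739, 5 of 5), S100a8 (4.02 ± 0.79, adjusted p = 0.00114, 5 of 5) and Ccl3 (3.95 ± 0.70, adjusted p = 0.000577, 5 of 5). Next came the protein cross-linking enzyme Tgm1 (3.65 ± 1.17, adjusted p = 0.0377, 4 of 5) and the oxidised-lipoprotein receptor Olr1 (3.61 ± 0.91, adjusted p = 0.00971, 5 of 5). Besides Hpx (probe set M62642_at, -5.17 ± 1.51, adjusted p = 0.0226, 5 of 5), whose erratic readings are given above, the largest falls were the brake on fat breakdown G0s2 (-3.65 ± 0.70, adjusted p = 0.000982, 5 of 5) and the hemoglobin-binding protein Hp (-3.02 ± 0.83, adjusted p = 0.0163, 5 of 5). The vasopressin receptor Avpr1a (-2.98 ± 0.81, adjusted p = 0.0157, 5 of 5) and C5h1orf210 (-2.77 ± 0.71, adjusted p = 0.0111, 5 of 5) fell as well. Calls depended on single arrays and ended without 1 h replicate 2 for Tgm1, Hpx and Avpr1a (adjusted p 0.0606 to 0.121), without 2 h replicate 1 for Tgm1, Olr1, Hpx and Avpr1a (adjusted p 0.052 to 0.0893) and without 2 h replicate 2 for Tgm1 and Hp (adjusted p 0.089 to 0.133). More ended without control 1 for Tgm1 and Avpr1a (adjusted p 0.0748 to 0.0934) and without control 3 or control 4 for Tgm1, Hpx and Hp (adjusted p 0.0925 to 0.123).

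Among 31 inflammatory mediators and interferon targets, 13 rose and 18 did not pass (14 rose adjusted over the list alone), and the median was 0.96 (camera adjusted p = 3.14e-07, 0.48 with an estimated correlation). Ccl4 (3.36 ± 0.64, 5 of 5) and Cxcl2 (3.35 ± 0.84, 5 of 5) rose. Of the 15 glucocorticoid-induced genes, 9 rose and 6 did not pass (12 rose adjusted over the list alone), with a median of 1.03 (camera adjusted p = 9.26e-07, 0.468 with an estimated correlation). Cebpd (3.54 ± 0.70, 5 of 5) and Nfkbia (3.29 ± 0.41, 5 of 5) rose. Nfkbia encodes the inhibitor that holds NF-kappaB in the cytoplasm. Immediate-early genes moved up by a median of 0.71 (camera adjusted p = 0.00237, 0.575 with an estimated correlation), and 3 rose and 17 did not pass of 20 (12 rose adjusted over the list alone). Myc (2.47 ± 0.65, 5 of 5) and Zfp36 (2.02 ± 0.31, 5 of 5) rose. Neutrophil markers moved up by a median of 1.03, where 2 of 6 rose (camera adjusted p = 0.0353, 0.496 with an estimated correlation). With 1 array left out, calls ended without 2 h replicate 1 for Cxcl2 (adjusted p = 0.0798).

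Among 39 genes of mitochondrial oxidative phosphorylation, 10 fell and 29 did not pass (12 fell adjusted over the list alone), and the median was -0.23 (camera adjusted p = 4.38e-07, 0.468 with an estimated correlation). Ndufb10 (-0.99 ± 0.20, 5 of 5) and Ndufs7 (-0.90 ± 0.17, 5 of 5) fell. Of the 43 drug-metabolising enzymes, 6 fell and 37 did not pass (6 fell adjusted over the list alone), with a median of -0.33 (camera adjusted p = 2.03e-05, 0.496 with an estimated correlation). Gstt2 (-1.65 ± 0.45, 5 of 5) and Cyp2a2 (-1.60 ± 0.46, 5 of 5) fell. Fatty acid oxidation and ketogenesis genes moved down by a median of -0.39 (camera adjusted p = 0.000121, 0.496 with an estimated correlation), and 3 fell and 18 did not pass of 21 (9 fell adjusted over the list alone). Pdk4 (-2.68 ± 0.57, 5 of 5) and Bdh1 (-1.30 ± 0.32, 5 of 5) fell. Among the named genes calls ended without 2 h replicate 1 for Bdh1, Gstt2 and Cyp2a2 (adjusted p 0.052 to 0.0885), without control 3 for Gstt2 and Cyp2a2 (adjusted p 0.057 to 0.0763) and without 1 h replicate 2 or control 4 for Cyp2a2 (adjusted p 0.065 to 0.0772).

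At 1-2 h 4 lists passed as higher, 7 as lower and 17 did not pass, and 0 passed with an estimated correlation. Among the 7, hepatocyte secretory proteins had a median of -0.26 with 0 of 17 genes past the threshold (camera adjusted p = 0.0232), which turned to 0.06 after quantile normalization (adjusted p = 0.967). It did not pass with the replicate block (adjusted p = 0.279) or the mean over a gene's probe sets (adjusted p = 0.0799) either. The count of 739 fell to 396 without 1 h replicate 2, 266 without 2 h replicate 1, 395 without control 3 and 407 without control 4. Higher and lower probe sets numbered 352 and 379 after quantile normalization and 331 and 414 after median centring. Without the low-correlation arrays the neutrophil call ended (adjusted p = 0.0567) and 355 probe sets passed.

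At 4-8 h 1642 probe sets passed against control, 1000 higher and 642 lower, the most of the short-course windows. It also holds the most arrays, 17. Gucy2c, a membrane guanylate cyclase, was 11.2 times and the fatty acid carrier Fabp4 7.54 times the control level, while Pdk4 stood at 0.151 of it. The rises were largest for Gucy2c (probe set M55636_at, 3.49 ± 0.50, adjusted p = 6.44e-06, 17 of 17), Tgm1 (3.09 ± 0.96, adjusted p = 0.0161, 17 of 17) and S100a8 (2.98 ± 0.65, adjusted p = 0.00092, 17 of 17). Next were Fabp4 (2.91 ± 0.46, adjusted p = 2.28e-05, 17 of 17), the phospholipase Pla1a (2.84 ± 0.42, adjusted p = 9.82e-06, 17 of 17) and the oxysterol hydroxylase Cyp7b1 (2.52 ± 0.37, adjusted p = 1e-05, 17 of 17). The interleukin-1 receptor antagonist Il1rn (2.83 ± 0.54, adjusted p = 0.000253, 17 of 17) rose too, together with the zinc finger gene Zfp354a (2.57 ± 0.49, adjusted p = 0.000233, 17 of 17). The retinol dehydrogenase Rdh16 (2.34 ± 0.53, adjusted p = 0.00139, 17 of 17) and the ubiquitin-conjugating enzyme Ube2g2 (2.22 ± 0.30, adjusted p = 3.6e-06, 17 of 17) complete the 10 largest rises. Calls ended without control 1, control 3 or control 4 for Tgm1 (adjusted p 0.0627 to 0.0763).

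Among the 10 largest falls, the erratic plasma protein probe sets came first, Hpx (probe set M62642_at, -4.40 ± 1.24, adjusted p = 0.00791, 16 of 17) and Kng2 (-4.19 ± 1.59, adjusted p = 0.048, 16 of 17). They were followed by C5h1orf210 (-3.01 ± 0.59, adjusted p = 0.000301, 17 of 17) and the bile acid-conjugating enzyme Baat (-2.75 ± 0.67, adjusted p = 0.00241, 17 of 17). Then came Pdk4 (-2.73 ± 0.47, adjusted p = 6.62e-05, 17 of 17) and the steroid dehydrogenase Hsd17b2 (-2.63 ± 0.73, adjusted p = 0.00745, 17 of 17). So did the aldehyde reductase Akr7a3 (-2.35 ± 0.42, adjusted p = 0.000112, 17 of 17) and the histidine-degrading enzyme Hal (-2.32 ± 0.39, adjusted p = 4.63e-05, 17 of 17). The alcohol dehydrogenase Adh4 (-2.31 ± 0.45, adjusted p = 0.000299, 17 of 17) and the glutathione synthesis subunit Gclm (-2.23 ± 0.42, adjusted p = 0.000194, 17 of 17) close the group. Leaving out 1 array ended calls without control 3 for Hpx, Kng2 and Hsd17b2 (adjusted p 0.0612 to 0.154), without control 4 for Hpx and Kng2 (adjusted p 0.0868 to 0.138) and without 4 h replicate 2, 4 h replicate 3, 5.5 h replicate 2, 5.5 h replicate 3, 5 h replicate 2, 6 h replicate 1, 6 h replicate 2, 6 h replicate 3, 7 h replicate 3, 8 h replicate 1, 8 h replicate 3 or control 1 for Kng2 (adjusted p 0.0516 to 0.0985).

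Among 15 glucocorticoid-induced genes, 10 rose and 5 did not pass (10 rose adjusted over the list alone), and the median was 0.79 (camera adjusted p = 0.00435, 0.496 with an estimated correlation). Cebpd (1.96 ± 0.58, 17 of 17) and Nfkbia (1.53 ± 0.34, 17 of 17) rose. Of the 22 proteasome subunits, 12 rose and 10 did not pass (14 rose adjusted over the list alone), with a median of 0.42 (camera adjusted p = 2.32e-05, 0.472 with an estimated correlation). Psma6 (0.87 ± 0.13, 17 of 17) and Psma7 (0.72 ± 0.14, 17 of 17) rose. Drug-metabolising enzymes moved down by a median of -0.51 (camera adjusted p = 1.25e-06, 0.472 with an estimated correlation), and 1 rose, 15 fell and 27 did not pass of 43 (2 rose and 17 fell adjusted over the list alone). Gstt2 (-2.16 ± 0.37, 17 of 17) and Fmo1 (-1.99 ± 0.59, 17 of 17) fell. Among 21 fatty acid oxidation and ketogenesis genes, 1 rose, 9 fell and 11 did not pass (1 rose and 10 fell adjusted over the list alone), and the median was -0.43 (camera adjusted p = 2.03e-05, 0.472 with an estimated correlation). Bdh1 (-2.21 ± 0.26, 17 of 17) and Ehhadh (-1.53 ± 0.37, 16 of 17) fell. Of the 18 bile acid synthesis and transport genes, 2 rose, 8 fell and 8 did not pass (2 rose and 8 fell adjusted over the list alone), with a median of -0.48 (camera adjusted p = 0.00382, 0.468 with an estimated correlation). Amacr (-1.92 ± 0.50, 17 of 17) and Hsd3b7 (-1.85 ± 0.23, 17 of 17) fell. Calls were lost without control 1 for Fmo1 (adjusted p = 0.1).

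Amino acid breakdown genes moved down by a median of -0.17 (camera adjusted p = 0.0295, 0.718 with an estimated correlation), and 5 rose, 11 fell and 11 did not pass of 27 (6 rose and 12 fell adjusted over the list alone). Fatty acid and triglyceride synthesis genes moved down by a median of -0.53, where 1 of 15 rose and 5 fell (camera adjusted p = 0.00444, 0.499 with an estimated correlation).

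At 4-8 h 2 lists passed as higher, 7 as lower and 19 did not pass, and 0 passed with an estimated correlation. The median change of all probe sets in this window was 0.103 as deposited, 0.028 after quantile normalization and -0.021 after median centring, so higher and lower counts read 794 and 739 with the first and 653 and 882 with the second scaling. The amino acid breakdown call ended with both (medians -0.07 and -0.29, adjusted p = 0.187 and 0.0811) and with the mean over a gene's probe sets (adjusted p = 0.0557). The median of the drug-metabolising enzymes was -0.29 after quantile normalization. Without the low-correlation arrays 1095 probe sets passed, and the calls of glucocorticoid-induced genes (adjusted p = 0.0551), amino acid breakdown (adjusted p = 0.179) and fatty acid synthesis (adjusted p = 0.0964) ended. Nr3c1 did not pass there either (adjusted p = 0.0958), and the rises of S100a8 and Il1rn were 1.97 and 2.02. Those 7 arrays include control 1, without which alone the Nr3c1 call ends (adjusted p = 0.0877), and 4 arrays of this window. The 4 carry its highest mean neutrophil signals, 8.361 to 8.825 (log2) against 6.942 to 8.258 on the other 13. Without control 3 the count was 1085.

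At 12-18 h 67 probe sets passed, 33 higher and 34 lower. A2m, the protease inhibitor alpha-2-macroglobulin, was 6.6 times its control level, and the growth hormone receptor Ghr stood at 0.363. The 5 largest rises were Gucy2c (probe set M55636_at, 2.94 ± 0.60, adjusted p = 0.00901, 5 of 5), A2m (2.72 ± 0.40, adjusted p = 0.000115, 5 of 5), Pla1a (1.94 ± 0.51, adjusted p = 0.04996, 5 of 5), the nucleotide kinase Nme1 (0.86 ± 0.18, adjusted p = 0.0119, 5 of 5) and the mitochondrial chaperonin Hspe1 (0.80 ± 0.18, adjusted p = 0.0218, 5 of 5). The falls began with Obp3 (probe set J00738_s_at, -2.75 ± 0.64, adjusted p = 0.0246, 5 of 5) and the clock repressor Nr1d2 (-1.73 ± 0.31, adjusted p = 0.00161, 5 of 5). The cyclin Ccnd1 (-1.47 ± 0.30, adjusted p = 0.00875, 5 of 5), Ghr (-1.46 ± 0.22, adjusted p = 0.000181, 5 of 5) and the matrix protease Mmp2 (-1.40 ± 0.31, adjusted p = 0.02, 5 of 5) followed. Calls depended on single arrays and ended without 12 h replicate 1 for Gucy2c, Pla1a, Nme1, Hspe1, Obp3 and Ccnd1 (adjusted p 0.0733 to 0.165), without control 4 for Gucy2c, Pla1a, Hspe1, Obp3 and Mmp2 (adjusted p 0.0545 to 0.147) and without 12 h replicate 2 for Pla1a, Obp3 and Mmp2 (adjusted p 0.084 to 0.115). Others ended without 18 h replicate 1 or control 1 for Pla1a and Obp3 (adjusted p 0.0676 to 0.188), without 18 h replicate 2 for Pla1a, Hspe1 and Obp3 (adjusted p 0.0586 to 0.0815) and without 18 h replicate 3 for Pla1a (adjusted p = 0.0555). They also ended without control 3 for Pla1a, Hspe1, Obp3 and Mmp2 (adjusted p 0.0541 to 0.103).

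Among 39 genes of mitochondrial oxidative phosphorylation, 3 rose and 36 did not pass (8 rose adjusted over the list alone), and the median was 0.26 (camera adjusted p = 1.02e-15, 0.105 with an estimated correlation). Cyc1 (0.76 ± 0.12, 5 of 5) and Ndufb9 (0.59 ± 0.14, 5 of 5) rose. Ribosomal proteins moved up by a median of 0.21, where 0 of 36 passed (camera adjusted p = 4.64e-11, 0.468 with an estimated correlation). Proteasome subunits moved up by a median of 0.22, where 2 of 22 rose (camera adjusted p = 2.42e-09, 0.468 with an estimated correlation). Cell cycle genes moved down by a median of -0.37, where 1 of 18 fell (camera adjusted p = 0.000294, 0.468 with an estimated correlation). With 1 array left out, calls ended without 12 h replicate 1, 12 h replicate 2, 18 h replicate 1, 18 h replicate 2, control 3 or control 4 for Ndufb9 (adjusted p 0.0608 to 0.155).

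At 12-18 h 7 lists passed as higher, 1 as lower and 20 did not pass, and 0 passed with an estimated correlation. Among the 7, acute-phase proteins passed with a median of -0.01 and 1 of 27 genes higher (camera adjusted p = 0.0109), a median that read 0.09 after median centring. That call ended after quantile normalization (adjusted p = 0.112) and without the low-correlation arrays (adjusted p = 0.914). The count of 67 was 15 without 12 h replicate 1, 39 without 12 h replicate 2, 38 without 18 h replicate 1, 30 without 18 h replicate 2, 28 without control 3 and 29 without control 4. Median centring gave 70 higher and 17 lower.

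By 30-72 h 6 probe sets differed from control, 5 higher and 1 lower. Unadjusted limma p was under 0.05 for 305, about as many as chance gives. The procollagen-processing helper Pcolce (probe set AF016503_s_at, 1.70 ± 0.33, adjusted p = 0.0255, 7 of 7), the prolactin receptor Prlr (1.38 ± 0.28, adjusted p = 0.0255, 7 of 7) and Ighvl1 (1.17 ± 0.17, adjusted p = 0.000288, 7 of 7) rose, and Obp3 (-3.07 ± 0.60, adjusted p = 0.0255, 7 of 7) fell. A second A2m probe set, less bright than the one used above, rose by 1.91 ± 0.40 (adjusted p = 0.0387), and the last of the 6 has no gene symbol. Among the named genes calls ended without 30 h replicate 1, 48 h replicate 1, 72 h replicate 1 or control 1 for Pcolce, Prlr and Obp3 (adjusted p 0.0537 to 0.137), without control 3 for Pcolce (adjusted p = 0.0784) and without 48 h replicate 3 or control 4 for Prlr and Obp3 (adjusted p 0.0666 to 0.126). Calls ended too without 72 h replicate 2 for Prlr (adjusted p = 0.0646).

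Ribosomal proteins moved down by a median of -0.14, where 0 of 36 passed (camera adjusted p = 4.32e-09, 0.468 with an estimated correlation). Proteasome subunits moved down by a median of -0.17, where 0 of 22 passed (camera adjusted p = 5e-07, 0.468 with an estimated correlation). At unadjusted p under 0.05, 3 ribosomal and 4 proteasome genes were lower.

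At 30-72 h 2 lists passed as higher, 4 as lower and 22 did not pass, and 0 passed with an estimated correlation. The count of 6 was 1 without 30 h replicate 1, 48 h replicate 1 or 72 h replicate 1, 2 without 48 h replicate 3 or control 1, 11 without 48 h replicate 2, 14 without control 2 and 15 without 30 h replicate 2. Quantile normalization and median centring each left 2 higher and 1 lower.

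The direct comparison of 30-72 h with 4-8 h, in which the controls take no part, asked how far the response had returned. It gave 2239 probe sets, 925 higher and 1314 lower at the later times (1091 and 1107 after median centring). Tat was lower by 0.93 ± 0.19 (adjusted p = 0.000221, 7 of 7 arrays) and Nr3c1 higher by 0.53 ± 0.16 (adjusted p = 0.00773, 6 of 7 arrays). The largest rises were C5h1orf210 (probe set rc_AA892861_at, 3.13 ± 0.48, adjusted p = 4.63e-06, 7 of 7), Hpx (2.91 ± 1.01, adjusted p = 0.0228, 4 of 7) and Baat (2.85 ± 0.55, adjusted p = 0.000102, 7 of 7). Then came Hsd17b2 (2.82 ± 0.60, adjusted p = 0.000373, 7 of 7) and the protease inhibitor Serpina3n (2.54 ± 0.88, adjusted p = 0.0218, 7 of 7). Largest falls were Gucy2c (probe set M55636_at, -3.43 ± 0.41, adjusted p = 7.13e-08, 7 of 7), Rdh16 (-2.89 ± 0.44, adjusted p = 3.39e-06, 7 of 7) and Pla1a (-2.87 ± 0.34, adjusted p = 7.85e-08, 7 of 7). The fatty acid carrier Fabp4 (-2.81 ± 0.38, adjusted p = 4.85e-07, 7 of 7) and Tgm1 (-2.80 ± 0.79, adjusted p = 0.00539, 7 of 7) fell too. Calls ended without 30 h replicate 1 for Hpx (adjusted p = 0.146), without 72 h replicate 2 for Hpx and Serpina3n (adjusted p 0.0679 to 0.0795) and without 30 h replicate 2 or 5 h replicate 2 for Serpina3n (adjusted p 0.0545 to 0.0597). More ended without 72 h replicate 1 for Nr3c1 (adjusted p = 0.127).

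Of the 22 proteasome subunits, 21 fell and 1 did not pass (21 fell adjusted over the list alone), with a median of -0.57 (camera adjusted p = 1.77e-10, 0.234 with an estimated correlation). Psma7 (-1.13 ± 0.12, 7 of 7) and Psmc4 (-0.96 ± 0.11, 7 of 7) fell. Ribosomal proteins moved down by a median of -0.26 (camera adjusted p = 5.11e-05, 0.642 with an estimated correlation), and 20 fell and 16 did not pass of 36 (23 fell adjusted over the list alone). Rpl6 (-0.82 ± 0.08, 7 of 7) and Rps24 (-0.69 ± 0.13, 7 of 7) fell. Among 15 glucocorticoid-induced genes, 10 fell and 5 did not pass (10 fell adjusted over the list alone), and the median was -0.81 (camera adjusted p = 0.0023, 0.457 with an estimated correlation). Dusp1 (-1.67 ± 0.32, 7 of 7) and Klf9 (-1.38 ± 0.21, 7 of 7) fell.

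Of the 43 drug-metabolising enzymes, 25 rose, 2 fell and 16 did not pass (26 rose and 4 fell adjusted over the list alone), with a median of 0.47 (camera adjusted p = 9.74e-07, 0.372 with an estimated correlation). Sult2a1 (2.18 ± 0.67, 7 of 7) and Gstt2 (1.88 ± 0.31, 7 of 7) rose. Fatty acid and triglyceride synthesis genes moved up by a median of 0.96 (camera adjusted p = 5.11e-05, 0.372 with an estimated correlation), and 11 rose and 4 did not pass of 15 (11 rose adjusted over the list alone). Srebf1 (2.19 ± 0.24, 7 of 7) rose. Bile acid synthesis and transport genes moved up by a median of 0.80, where 10 of 18 rose and 2 fell (camera adjusted p = 0.00125, 0.372 with an estimated correlation). Fatty acid oxidation and ketogenesis genes moved up by a median of 0.34, where 9 of 21 rose (camera adjusted p = 0.00511, 0.643 with an estimated correlation). Of the lists 6 passed as higher, 4 as lower and 18 did not pass in this comparison, and 0 passed with an estimated correlation.

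At 6-18 h of the long course A2m, a protease inhibitor of the rat acute phase, was 26.3 times its control level. The comparison gave 1031 probe sets, 513 higher and 518 lower. The largest rises were A2m (4.72 ± 0.44, adjusted p = 1.24e-09, 16 of 16), Rdh16 (2.88 ± 0.24, adjusted p = 6.74e-11, 16 of 16) and the methionine cycle enzyme Bhmt (2.67 ± 0.45, adjusted p = 0.000101, 16 of 16). Next were Zfp354a (2.65 ± 0.40, adjusted p = 2.09e-05, 16 of 16) and 2 genes of endoplasmic reticulum turnover, Edem1 (2.52 ± 0.22, adjusted p = 1.66e-10, 16 of 16) and Retreg1 (2.31 ± 0.28, adjusted p = 6.63e-07, 16 of 16). Aspartate aminotransferase Got1 (2.19 ± 0.45, adjusted p = 0.00121, 14 of 16) rose with Coq10b (2.14 ± 0.25, adjusted p = 1.89e-07, 16 of 16). The last 2 of the 10 were the glycolysis regulator Pfkfb1 (2.13 ± 0.24, adjusted p = 1.69e-07, 16 of 16) and the electron donor of the cytochrome P450 enzymes Por (1.93 ± 0.32, adjusted p = 9.58e-05, 16 of 16).

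The largest falls were the thyroxine-binding globulin Serpina7 (-2.01 ± 0.36, adjusted p = 0.000224, 16 of 16), Osgin1 (-1.78 ± 0.39, adjusted p = 0.00193, 16 of 16) and the bile acid-induced repressor Nr0b2 (-1.56 ± 0.31, adjusted p = 0.000672, 16 of 16). Next were Slfn4 (-1.54 ± 0.23, adjusted p = 2.58e-05, 16 of 16), the class I gene RT1-S3 (-1.44 ± 0.21, adjusted p = 1.42e-05, 16 of 16) and the chemokine Ccl6 (-1.40 ± 0.19, adjusted p = 5.57e-06, 16 of 16). The peroxisomal oxidation enzyme Ehhadh (-1.39 ± 0.30, adjusted p = 0.00167, 16 of 16) and the transcription regulator Tsc22d1 (-1.34 ± 0.24, adjusted p = 0.00023, 16 of 16) fell as well. The aldo-keto reductase Akr1b7 (-1.32 ± 0.41, adjusted p = 0.0343, 16 of 16) and the fatty acid desaturase Fads1 (-1.30 ± 0.38, adjusted p = 0.0215, 16 of 16) close the 10. Leaving out 1 array ended calls without control 1, control 3 or control 4 for Akr1b7 and Fads1 (adjusted p 0.0532 to 0.242).

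Among 24 glucocorticoid-induced genes, 12 rose, 2 fell and 10 did not pass (19 rose and 2 fell adjusted over the list alone), and the median was 0.74 (camera adjusted p = 1.88e-11, 0.0108 with an estimated correlation). Lpin1 (1.92 ± 0.34, 13 of 16) and Fkbp5 (1.73 ± 0.26, 16 of 16) rose. Fkbp5 is a chaperone partner of the glucocorticoid receptor. Of the 30 amino acid breakdown genes, 12 rose, 4 fell and 14 did not pass (13 rose and 4 fell adjusted over the list alone), with a median of 0.38 (camera adjusted p = 2.65e-06, 0.164 with an estimated correlation). Gpt (1.74 ± 0.27, 16 of 16) rose. Gluconeogenesis genes moved up by a median of 0.28 (camera adjusted p = 0.000189, 0.12 with an estimated correlation), and 5 rose, 1 fell and 7 did not pass of 13 (5 rose and 1 fell adjusted over the list alone). Slc37a4 (0.86 ± 0.19, 16 of 16) and Mdh1 (0.75 ± 0.15, 16 of 16) rose. Urea cycle genes moved up by a median of 0.52, where 3 of 7 rose and 1 fell (camera adjusted p = 0.00739, 0.143 with an estimated correlation). Calls were lost without control 2 for Slc37a4 (adjusted p = 0.0566).

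Genes of mitochondrial oxidative phosphorylation moved up by a median of 0.15, where 3 of 55 rose (camera adjusted p = 3.21e-05, 0.278 with an estimated correlation). Ribosomal proteins moved up by a median of 0.18, where 2 of 36 rose (camera adjusted p = 6.88e-06, 0.303 with an estimated correlation). Pancreas markers moved up by a median of 0.65, where 0 of 14 passed (camera adjusted p = 0.0383, 0.712 with an estimated correlation). Mean pancreas signal ran from 5.95 to 9.82 on the log2 scale across the long-course arrays.

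Among 37 inflammatory mediators and interferon targets, 1 rose, 9 fell and 27 did not pass (1 rose and 11 fell adjusted over the list alone), and the median was -0.24 (camera adjusted p = 5.41e-05, 0.143 with an estimated correlation). Psmb8 (-1.09 ± 0.18, 16 of 16) and Irf7 (-0.99 ± 0.16, 15 of 16) fell. Of the 18 markers of Kupffer cells and macrophages, 8 fell and 10 did not pass (11 fell adjusted over the list alone), with a median of -0.40 (camera adjusted p = 1.11e-06, 0.104 with an estimated correlation). Clec4f (-0.69 ± 0.14, 16 of 16) and Cd68 (-0.72 ± 0.17, 16 of 16) fell. Genes of MHC class II presentation moved down by a median of -0.36, where 2 of 10 fell (camera adjusted p = 0.000268, 0.126 with an estimated correlation).

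At 6-18 h 9 lists passed as higher, 5 as lower and 13 did not pass, and 1 passed with an estimated correlation. The count of 1031 was 634 without control 1 and 642 without control 3. With the spike-in batch as a block it was 1227, with the low spike-in arrays alone 917, and with the high arrays alone 10. All the lists kept their calls with the block. With the low arrays alone the ribosomal proteins (adjusted p = 0.0573), pancreas markers (adjusted p = 0.27), chaperones (adjusted p = 0.0913) and lymphocyte markers (adjusted p = 0.0898) did not pass. With the high arrays alone gluconeogenesis, MHC class II, cell cycle and lymphocyte markers did not. The high arrays hold 1 control, so a call kept there bears out no list. Median centring gave 547 higher and 336 lower, and ended the pancreas call (adjusted p = 0.07), as quantile normalization did (adjusted p = 0.0526). The urea cycle median was 0.89 after quantile normalization.

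At 24-48 h alanine aminotransferase (Gpt), which feeds amino acid carbon into glucose synthesis, was 11.1 times and A2m 22 times the control level. In all 583 probe sets passed, 290 higher and 293 lower. The 5 largest rises were A2m (4.46 ± 0.46, adjusted p = 9.84e-09, 12 of 12), Gpt (3.47 ± 0.28, adjusted p = 2.91e-11, 12 of 12), Bhmt (2.96 ± 0.46, adjusted p = 3.68e-05, 12 of 12), Zfp354a (2.85 ± 0.41, adjusted p = 1e-05, 12 of 12) and Rdh16 (2.52 ± 0.25, adjusted p = 3.58e-09, 12 of 12). The falls were led by Serpina7 (-2.93 ± 0.37, adjusted p = 1.05e-06, 12 of 12) and the insulin-like growth factor carrier Igfbp2 (-2.15 ± 0.40, adjusted p = 0.000409, 12 of 12). Next were Osgin1 (-2.04 ± 0.40, adjusted p = 0.000842, 12 of 12), Ccl6 (-1.96 ± 0.20, adjusted p = 8.43e-09, 12 of 12) and Slfn4 (-1.83 ± 0.24, adjusted p = 2.14e-06, 12 of 12).

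Amino acid breakdown genes moved up by a median of 0.69 (camera adjusted p = 6.22e-22, 0.0108 with an estimated correlation), and 15 rose and 15 did not pass of 30 (19 rose adjusted over the list alone). Prodh (2.00 ± 0.31, 12 of 12) and Sds (2.42 ± 0.50, 10 of 12) rose. Among 55 genes of mitochondrial oxidative phosphorylation, 21 rose and 34 did not pass (31 rose adjusted over the list alone), and the median was 0.31 (camera adjusted p = 1.55e-24, 0.0108 with an estimated correlation). Atp5mg (0.56 ± 0.12, 12 of 12) and Ndufb9 (0.55 ± 0.14, 12 of 12) rose. Of the 24 glucocorticoid-induced genes, 8 rose and 16 did not pass (9 rose and 2 fell adjusted over the list alone), with a median of 0.44 (camera adjusted p = 7.82e-09, 0.0212 with an estimated correlation). Tsc22d3 (1.44 ± 0.20, 12 of 12) and Fkbp5 (1.32 ± 0.26, 12 of 12) rose. Gluconeogenesis genes moved up by a median of 0.27, where 3 of 13 rose (camera adjusted p = 1.59e-06, 0.0455 with an estimated correlation). Urea cycle genes moved up by a median of 0.63, where 3 of 7 rose (camera adjusted p = 0.000189, 0.0479 with an estimated correlation).

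Drug-metabolising enzymes moved up by a median of 0.23 (camera adjusted p = 1.2e-05, 0.0541 with an estimated correlation), and 12 rose, 4 fell and 29 did not pass of 45 (17 rose and 7 fell adjusted over the list alone). Sult1a1 (2.32 ± 0.32, 12 of 12) and Fmo1 (1.44 ± 0.35, 12 of 12) rose. Pancreas markers moved up by a median of 0.58, where 0 of 14 passed (camera adjusted p = 0.0102, 0.678 with an estimated correlation). Calls depended on single arrays and ended without control 2 for Fmo1 (adjusted p = 0.16).

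Among 18 markers of Kupffer cells and macrophages, 10 fell and 8 did not pass (12 fell adjusted over the list alone), and the median was -0.52 (camera adjusted p = 1.88e-11, 0.023 with an estimated correlation). Clec4f (-1.10 ± 0.15, 12 of 12) and Fcer1g (-0.89 ± 0.15, 12 of 12) fell. Of the 37 inflammatory mediators and interferon targets, 9 fell and 28 did not pass (14 fell adjusted over the list alone), with a median of -0.33 (camera adjusted p = 3.39e-09, 0.0333 with an estimated correlation). Irf7 (-1.05 ± 0.17, 12 of 12) and Psmb10 (-0.98 ± 0.17, 12 of 12) fell. Genes of MHC class II presentation moved down by a median of -0.53 (camera adjusted p = 1.14e-08, 0.0212 with an estimated correlation), and 5 fell and 5 did not pass of 10 (7 fell adjusted over the list alone). Cd74 (-1.58 ± 0.22, 12 of 12) and RT1-Da (-1.43 ± 0.25, 12 of 12) fell.

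Lymphocyte markers moved down by a median of -0.23, where 4 of 14 fell (camera adjusted p = 0.00899, 0.136 with an estimated correlation). Endothelial markers moved down by a median of -0.29, where 1 of 14 fell (camera adjusted p = 0.00525, 0.12 with an estimated correlation). Markers of stellate cells and fibroblasts moved down by a median of -0.29, where 3 of 20 fell (camera adjusted p = 0.00566, 0.171 with an estimated correlation). Cell cycle genes moved down by a median of -0.34, where 3 of 19 fell (camera adjusted p = 0.000268, 0.104 with an estimated correlation).

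At 24-48 h 9 lists passed as higher, 7 as lower and 11 did not pass, and 8 passed with an estimated correlation. The count of 583 was 358 without control 2. With the spike-in block it was 682, with the low arrays alone 640 and with the high arrays alone 1. All lists kept their calls with the block. The pancreas call ended with the low arrays alone (adjusted p = 0.536). Those of cholesterol synthesis and of bile acid synthesis and transport ended with the high arrays alone. The high arrays hold 1 control, so a call kept there bears out no list. Median centring gave 321 higher and 196 lower.

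At 72-168 h of the long course 1207 probe sets differed from control, 538 higher and 669 lower (555 and 541 after median centring). Cyp4a8, a fatty acid hydroxylase, was 13.8 times and Gpt 12.8 times its control level, while Serpina7 stood at 0.0456 and Serpina6, the corticosteroid-binding globulin of plasma, at 0.0821. The largest rises were Cyp4a8 (3.78 ± 0.28, adjusted p = 2.41e-12, 12 of 12), Gpt (3.67 ± 0.28, adjusted p = 2.41e-12, 12 of 12) and the translation repressor Eif4ebp3 (3.48 ± 0.36, adjusted p = 4.07e-09, 12 of 12). Then followed Obp3 (3.48 ± 0.46, adjusted p = 8.03e-07, 12 of 12), A2m (3.30 ± 0.46, adjusted p = 1.92e-06, 12 of 12) and Zfp354a (3.11 ± 0.41, adjusted p = 8.03e-07, 12 of 12). The lipid phosphatase Lpin1 (3.02 ± 0.35, adjusted p = 6.09e-08, 12 of 12) and Bhmt (2.97 ± 0.46, adjusted p = 1.57e-05, 12 of 12) rose, and so did the pancreatic enzyme Amy2a3 (2.81 ± 0.82, adjusted p = 0.0191, 10 of 12) and Rdh16 (2.72 ± 0.25, adjusted p = 1.56e-10, 12 of 12). With 1 array left out, calls ended without control 1 or control 4 for Amy2a3 (adjusted p 0.0696 to 0.0704).

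The 10 largest falls began with 3 carriers of hormones and growth factors, Serpina7 (-4.46 ± 0.37, adjusted p = 2.68e-11, 12 of 12), Igfbp2 (-3.63 ± 0.40, adjusted p = 1.53e-08, 12 of 12) and Serpina6 (-3.61 ± 0.38, adjusted p = 5.65e-09, 12 of 12). The interferon-induced gene Ifi27l2b (-2.58 ± 0.25, adjusted p = 1.06e-09, 12 of 12) fell with Slfn4 (-2.21 ± 0.24, adjusted p = 1.53e-08, 12 of 12) and Ccl6 (-2.04 ± 0.20, adjusted p = 1.06e-09, 12 of 12). Next were the epoxide hydrolase Ephx1 (-2.25 ± 0.31, adjusted p = 1.92e-06, 12 of 12), the retinal dehydrogenase Aldh1a1 (-2.21 ± 0.32, adjusted p = 3.74e-06, 12 of 12) and the desaturase Fads2 (-1.89 ± 0.26, adjusted p = 1.88e-06, 12 of 12). The tenth was Osgin1 (-2.02 ± 0.40, adjusted p = 0.000406, 12 of 12).

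Among 30 amino acid breakdown genes, 19 rose, 1 fell and 10 did not pass (22 rose and 1 fell adjusted over the list alone), and the median was 0.80 (camera adjusted p = 2.75e-16, 0.0212 with an estimated correlation). Sds (2.61 ± 0.50, 12 of 12) and Prodh (2.40 ± 0.31, 12 of 12) rose. Of the 24 glucocorticoid-induced genes, 13 rose, 1 fell and 10 did not pass (13 rose and 1 fell adjusted over the list alone), with a median of 0.79 (camera adjusted p = 7.94e-11, 0.0108 with an estimated correlation). Fkbp5 (2.03 ± 0.26, 12 of 12) and Tsc22d3 (1.68 ± 0.20, 12 of 12) rose. Gluconeogenesis genes moved up by a median of 0.56 (camera adjusted p = 1.32e-10, 0.0108 with an estimated correlation), and 10 rose and 3 did not pass of 13 (11 rose adjusted over the list alone). Slc37a4 (1.83 ± 0.20, 12 of 12) and Mdh1 (1.20 ± 0.15, 12 of 12) rose. Among 55 genes of mitochondrial oxidative phosphorylation, 26 rose and 29 did not pass (34 rose adjusted over the list alone), and the median was 0.34 (camera adjusted p = 2.06e-18, 0.023 with an estimated correlation). Ndufv2 (0.83 ± 0.14, 12 of 12) and Ndufb9 (0.75 ± 0.14, 12 of 12) rose. Urea cycle genes moved up by a median of 0.46, where 2 of 7 rose (camera adjusted p = 0.00726, 0.143 with an estimated correlation).

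Of the 10 genes of MHC class II presentation, 5 fell and 5 did not pass (8 fell adjusted over the list alone), with a median of -0.58 (camera adjusted p = 1.37e-07, 0.0263 with an estimated correlation). Cd74 (-1.70 ± 0.22, 12 of 12) and RT1-Da (-1.67 ± 0.25, 12 of 12) fell. Inflammatory mediators and interferon targets moved down by a median of -0.29 (camera adjusted p = 5.56e-06, 0.104 with an estimated correlation), and 13 fell and 24 did not pass of 37 (1 rose and 14 fell adjusted over the list alone). Irf7 (-1.19 ± 0.17, 12 of 12) and Psmb10 (-1.04 ± 0.17, 12 of 12) fell. Among 18 markers of Kupffer cells and macrophages, 8 fell and 10 did not pass (10 fell adjusted over the list alone), and the median was -0.40 (camera adjusted p = 1.02e-06, 0.104 with an estimated correlation). Clec4f (-1.38 ± 0.15, 12 of 12) and Cd68 (-0.81 ± 0.18, 11 of 12) fell. Lymphocyte markers moved down by a median of -0.26, where 6 of 14 fell (camera adjusted p = 0.00382, 0.104 with an estimated correlation). Markers of stellate cells and fibroblasts moved down by a median of -0.27, where 5 of 20 fell (camera adjusted p = 0.0309, 0.305 with an estimated correlation).

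Of the 20 cholesterol synthesis genes, 3 fell and 17 did not pass (1 rose and 10 fell adjusted over the list alone), with a median of -0.52 (camera adjusted p = 0.00301, 0.538 with an estimated correlation). Msmo1 (-1.76 ± 0.34, 12 of 12) fell. Cell cycle genes moved down by a median of -0.22, where 4 of 19 fell (camera adjusted p = 0.0117, 0.256 with an estimated correlation). Pancreas markers moved up by a median of 1.41, where 2 of 14 rose (camera adjusted p = 0.000244, 0.441 with an estimated correlation). The pancreas markers varied together from array to array, with a standard deviation of their mean of 0.66 in the controls and 1.31 in the 12 arrays of this window.

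At 72-168 h 6 lists passed as higher, 8 as lower and 13 did not pass, and 5 passed with an estimated correlation. With the spike-in block 1244 probe sets passed, with the low arrays alone 1000 and with the high arrays alone 28. All lists kept their calls with the block. With the low arrays alone the urea cycle (adjusted p = 0.128), cholesterol synthesis (adjusted p = 0.429), stellate cell (adjusted p = 0.072) and pancreas markers (adjusted p = 0.105) did not pass. With the high arrays alone the cell cycle genes and ribosomal proteins did not. The high arrays hold 1 control, so a call kept there bears out no list.

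**Figure D3:**
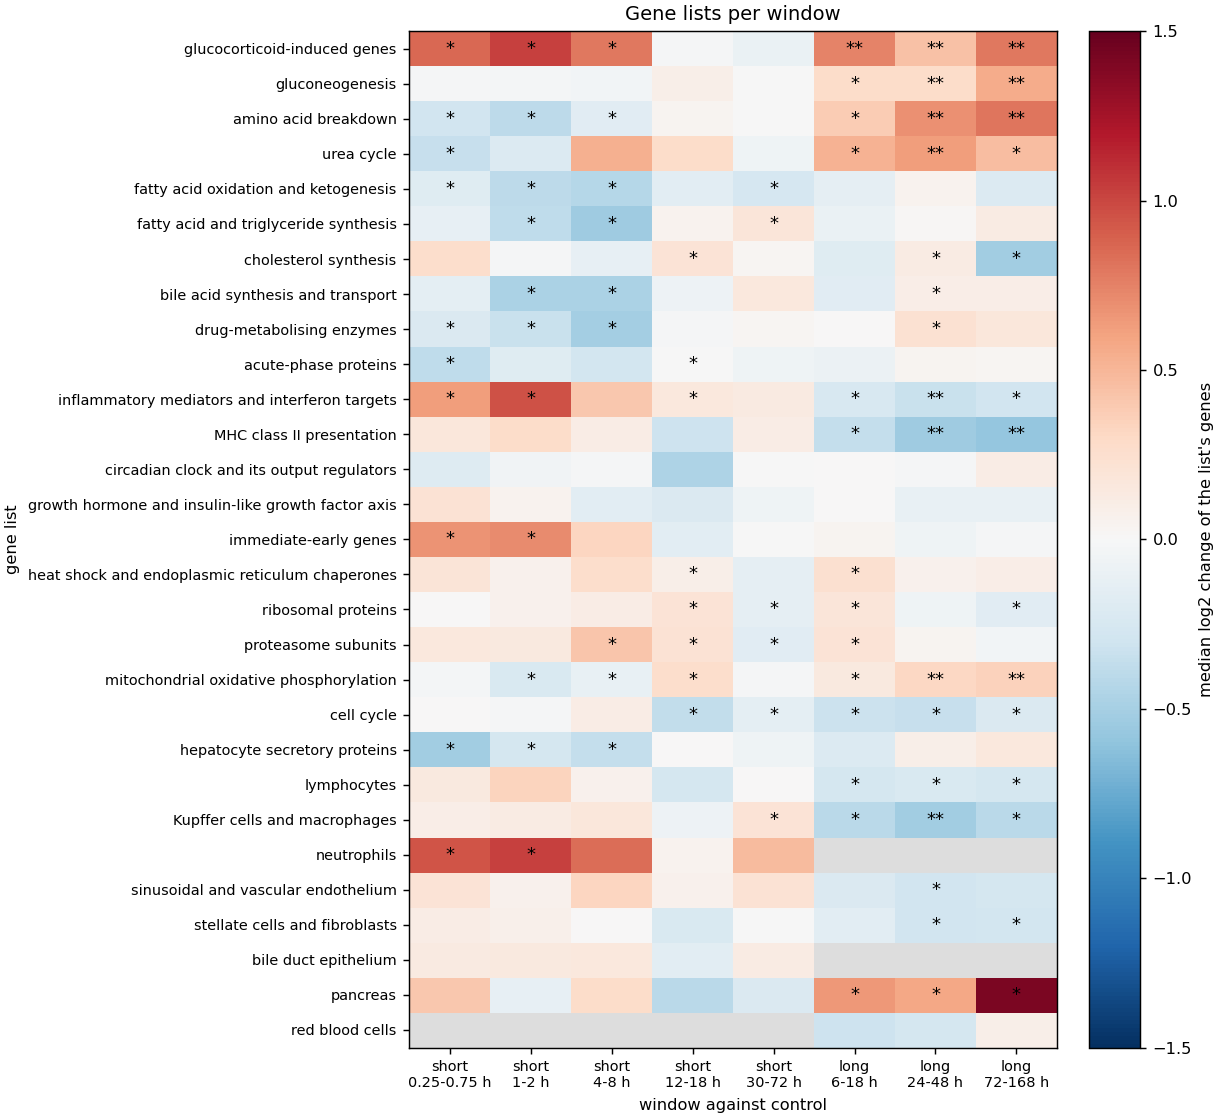
Median log2 change of each gene list fixed before the data were examined (vertical axis) in each time window against control (horizontal axis), with red for higher and blue for lower, grey where fewer than 5 genes were measured, 1 star for a camera adjusted p under 0.05 and 2 stars where it held with an estimated correlation. Amino acid breakdown had a median of -0.17 at 4-8 h of the short course and 0.80 at 72-168 h of the long course.

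**Figure D4:**
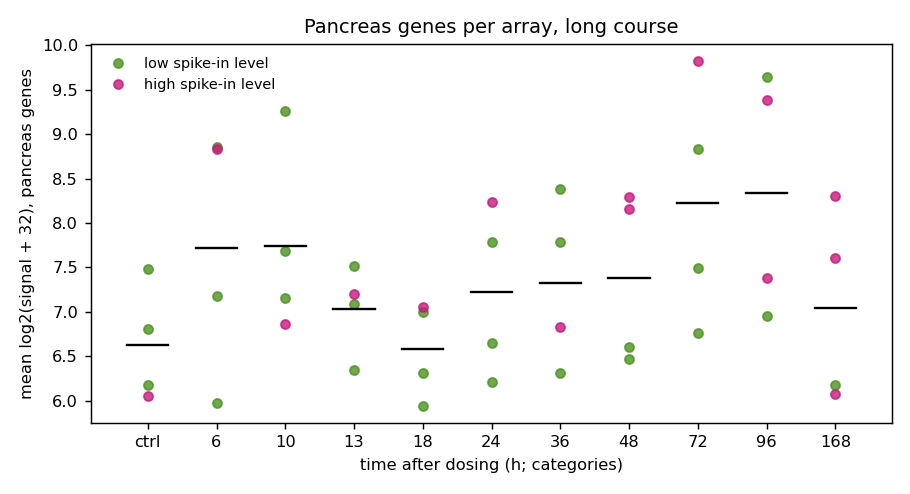
Mean of the pancreas markers on each long-course array, as log2(signal + 32), against the labelled time in hours, with low spike-in arrays in green, high ones in magenta and bars at the group means. Array means ran from 5.95 to 9.82.

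The direct comparison of 72-168 h with 6-18 h in the long course gave 2343 probe sets, 1005 higher and 1338 lower at the later times. Cyp4a8 was 13.3 times its level at 6-18 h, and Serpina6 stood at 0.13. Tat was lower by 0.50 ± 0.18 (adjusted p = 0.0447, 10 of 12 arrays), while Nr3c1 showed -0.03 (adjusted p = 0.915). The largest rises were Cyp4a8 (3.74 ± 0.19, adjusted p = 3.08e-18, 12 of 12), Amy2a3 (2.16 ± 0.54, adjusted p = 0.00335, 10 of 12) and Eif4ebp3 (2.00 ± 0.24, adjusted p = 6.31e-08, 12 of 12), with Obp3 (1.99 ± 0.30, adjusted p = 6.14e-06, 12 of 12) and the hemoglobin gene Hbb (1.98 ± 0.37, adjusted p = 0.0001, 11 of 12). Falls were largest for Igfbp2 (-2.98 ± 0.26, adjusted p = 9.99e-11, 12 of 12), Serpina6 (-2.95 ± 0.25, adjusted p = 3.93e-11, 12 of 12) and Serpina7 (-2.44 ± 0.25, adjusted p = 2.35e-09, 12 of 12). The retinal dehydrogenase Aldh1a1 (-2.37 ± 0.21, adjusted p = 9.99e-11, 12 of 12) and the cold-induced RNA-binding gene Rbm3 (-2.10 ± 0.28, adjusted p = 4.44e-07, 12 of 12) fell too. Among the named genes calls ended without 10 h replicate 1, 10 h replicate 2, 10 h replicate 3, 13 h replicate 3, 13 h replicate 4, 168 h replicate 1, 168 h replicate 4, 18 h replicate 1, 18 h replicate 2, 18 h replicate 4, 6 h replicate 1, 6 h replicate 4, 72 h replicate 1, 72 h replicate 3, 72 h replicate 4, 96 h replicate 2 or 96 h replicate 4 for Tat (adjusted p 0.0506 to 0.126).

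Ribosomal proteins moved down by a median of -0.32 (camera adjusted p = 4.29e-15, 0.277 with an estimated correlation), and 26 fell and 10 did not pass of 36 (29 fell adjusted over the list alone). Rpl3 (-0.65 ± 0.09, 12 of 12) and Rpl14 (-0.63 ± 0.08, 12 of 12) fell. Among 55 genes of mitochondrial oxidative phosphorylation, 23 rose, 1 fell and 31 did not pass (27 rose and 1 fell adjusted over the list alone), and the median was 0.18 (camera adjusted p = 2.4e-09, 0.277 with an estimated correlation). Ndufv2 (0.49 ± 0.09, 11 of 12) and Ndufs6 (0.46 ± 0.07, 12 of 12) rose. Of the 30 amino acid breakdown genes, 15 rose, 2 fell and 13 did not pass (19 rose and 4 fell adjusted over the list alone), with a median of 0.42 (camera adjusted p = 2.73e-06, 0.363 with an estimated correlation). Gpt (1.93 ± 0.18, 12 of 12) and Prodh (1.90 ± 0.21, 12 of 12) rose.

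Gluconeogenesis genes moved up by a median of 0.21 (camera adjusted p = 0.000279, 0.277 with an estimated correlation), and 7 rose and 6 did not pass of 13 (7 rose adjusted over the list alone). Pck1 (0.97 ± 0.14, 12 of 12) and Slc37a4 (0.97 ± 0.13, 12 of 12) rose. Of the lists 7 passed as higher, 3 as lower and 17 did not pass, and 0 passed with an estimated correlation. The count was 2179 with the spike-in block, 1257 with the low arrays alone and 74 with the high arrays alone.

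Genes called in the 4-8 h window of the short course were then read in the long course, which has its own controls, through the 2885 genes measured on both designs. Of the 521 genes higher at 4-8 h, 74.47% were higher at 6-18 h of the long course, against 43.47% of all genes, and 94 were called higher and 3 lower, where chance would give 29.62 called in the same direction (camera adjusted p = 2.1e-19, adjusted p = 4.76e-05 with an estimated correlation). Of the 375 genes lower at 4-8 h, 83.2% were lower at 6-18 h, against 56.53% of all genes, with 75 called lower, 3 higher and 22.62 by chance (camera adjusted p = 3.15e-13, adjusted p = 0.0288 with an estimated correlation). At 24-48 h neither set passed (camera adjusted p = 0.282 and adjusted p = 0.881). At 72-168 h the higher set had 47 genes called higher, where chance would give 34.13, and 30 lower (camera adjusted p = 0.0885), and the lower set 69 called lower, where chance would give 33.15, and 23 higher (camera adjusted p = 0.0416). These values are adjusted over the 2 sets and 3 windows. The former set passed after median centring (adjusted p = 0.0306), and after quantile normalization only before adjustment (0.0484, adjusted p = 0.0726). The latter did not pass with the mean over a gene's probe sets (adjusted p = 0.109), an estimated correlation (adjusted p = 0.602) or the fry test (adjusted p = 0.0544).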

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

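Comparisons of late with earlier windows, list tests on all arrays and the 12 tests on other array splits were set before results were seen. Every other test here was chosen only after. Late and earlier windows differed in a direct test, in 2239 probe sets for 30-72 h against 4-8 h of the short course and in 2343 for 72-168 h against 6-18 h of the long course. Between the same windows Tat differed by -0.93 and Nr3c1 by 0.53 in the short course, and Tat by -0.5 in the long course. Among 35 checks of Tat, Nr3c1 and the pancreas mean in the groups of 4 arrays, which are the long-course groups and the short-course controls, 0 arrays stood apart, and the smaller short-course groups were not checked.

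The inflammatory and immediate-early lists passed as higher in both windows from 0.25 to 2 h of the short course, but not with an estimated correlation (adjusted p 0.468 to 0.575). At 0.25-0.75 h 10 and at 1-2 h 13 of 31 inflammatory genes were called higher, and 3 of 20 immediate-early genes in each. Mean 3' to 5' log2 ratios below control (actin -0.235, GAPDH -0.171) argue against RNA breakdown in early samples but leave it open in controls. A few arrays that stand apart are argued against as the whole cause, since the mean of the inflammatory list lay above every control on 13 of the 14 arrays and that of the immediate-early list on 12. Some arrays rose far more than others, with inflammatory means from 8.41 to 10.56 against 8.27 to 8.76 in the controls. Blood neutrophils in the early samples may contribute, as 2 of 6 neutrophil markers were called higher, and cannot be told apart from a response of liver cells because these genes are also made by macrophages. Handling or injection without the drug has no group here, so a biological cause was not tested.

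Glucocorticoid-induced genes were higher at 72-168 h of the long course and not at 30-72 h of the short course. Too noisy short-course arrays are argued against for 6 of the 15 such genes measured on both designs. Over 48 and 72 h, the late times in both courses, their 95% intervals in the long course lie wholly above those in the short course, and 0 lie below. The other 9 genes and the times in 1 course alone leave it open. A spike-in batch is argued against by the 13 of 13 genes that kept at least 0.5 of their change among low spike-in arrays. Continued exposure in the long course may explain it, but the sets of short-course genes gave unadjusted p-values of 0.0208 and 0.059 at 72-168 h, and it cannot be told apart from other differences between the courses because the labels state no dosing schedule.

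The pancreas list passed as higher at 72-168 h of the long course with 2 of 14 markers called, but not with an estimated correlation (adjusted p = 0.441) or on the low spike-in arrays alone (adjusted p = 0.105). Their deviations from the group means rose and fell together with a median correlation of 0.915, against 0.132 for the highest of 1000 random sets, so pancreas tissue carried over with some samples is a candidate explanation. Their mean rose by 1.24 ± 0.6 over all arrays, by 1.1 ± 0.59 with the spike-in batch as a block and by 0.83 ± 0.66 on the low spike-in arrays alone, the last within its spread. The batch as the whole cause is argued against, since high arrays lay 0.58 ± 0.34 above low ones of the same group, where the rise would need 4.98. No biological explanation was tested.

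Other splits of the arrays into groups of the same sizes were drawn for each count, 100 with the real one. The real split called the most probe sets over time, 2040 (short course, highest other 90) and 2637 (long course, highest other 11). It also did at 4-8 h with 1642 (highest other 1389) and 6-18 h with 1031 (highest other 134). So it did at 24-48 h with 583 (highest other 17) and 72-168 h with 1207 (highest other 556). Between windows it called the most too, 2239 (highest other 684) and 2343 (highest other 23). Counting the real one, 4 splits reached the 205 at 0.25-0.75 h (highest other 394), 2 the 739 at 1-2 h (highest other 947) and 2 the 67 at 12-18 h (highest other 139). Each share above is under 0.05, which argues against chance for 1 count alone, without allowance for the 12 counts. The count of 205 ran from 41 to 567 when 1 array of that comparison was left out. Chance is not excluded for the 6 at 30-72 h, reached by 7 splits (highest other 388). A split with 388 calls where the real one has 6 points to a structure of the samples, which may be time itself or another.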

How the results depend on the processing

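Tests on the spike-in batch, on arrays of mean correlation under 0.9 and on the unscaled array were chosen only after the result was seen. With the array at 6 h replicate 3 left on its deposited scale, the short course gave 733 probe sets over time, 57 at 0.25-0.75 h, 212 at 1-2 h, 646 at 4-8 h, 12 at 12-18 h, 1 at 30-72 h and 1204 for 30-72 h against 4-8 h, since that array's values are several times lower. Without the arrays of mean correlation under 0.9 the early counts were 411 and 355, and the late ones 105 at 12-18 h and 2 at 30-72 h. With the arrays of the comparison alone, and so fewer arrays behind the spread, they were 43, 342, 35 and 1, and in the long course 370 at 24-48 h and 695 at 72-168 h. Quantile normalization gave 43 at 12-18 h and 3 at 30-72 h, and median centring 3 at 30-72 h. Array weights gave 344 at 0.25-0.75 h and 1 at 30-72 h, and called Tat or Nr3c1 in 5 comparisons instead of 8. The cause was not tested for the last 3 sets.

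As a replicate block, the replicate numbers gave 38, 407, 31 and 11 at 0.25-0.75, 1-2, 12-18 and 30-72 h. There, arrays of the same number had a mean correlation of deviations of -0.006, against 0.003 for other numbers, so the numbers pair no arrays and the cause was not tested. In the long course these were 0.053 and -0.017, and 22 of 44 arrays were closest to 1 of their own number, where 11 would be by chance. With the spike-in batch removed 13 were, so the numbers follow that batch.

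With high spike-in arrays alone, 15 in all, long-course counts were 7 over time, 10 at 6-18 h, 1 at 24-48 h, 28 at 72-168 h and 74 between late and earlier windows, and Tat or Nr3c1 passed in 4 comparisons. Low arrays alone gave 1257 between windows. Both hold fewer arrays. High arrays turned the sign of Slc37a4 at 6-18 h (-0.1), of Otc (-0.05), Sult1e1 (-0.09) and RT1-Db1 (0.07) at 24-48 h and of Rpl12 at 72-168 h (0.19), none past the threshold there. Of the list tests, 44 passed in each course. With an estimated correlation 0 of the short and 14 of the long course did, and with fry 21 and 38.

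Leaving out 1 array gave 1773 to 2231 probe sets over time in the short course, 41 to 567 at 0.25-0.75 h, 266 to 961 at 1-2 h, 1085 to 1787 at 4-8 h, 15 to 83 at 12-18 h, 1 to 15 at 30-72 h and 1875 to 2340 between windows. The long-course ranges were 2414 to 2839, 634 to 1111, 358 to 591, 897 to 1282 and 2046 to 2415, and Tat or Nr3c1 passed in 6 to 9 comparisons. Of 14054 alternatives for named genes, 12912 kept direction and side of the threshold, 1117 lost the call, 20 gained one and 5 turned sign. Of 748 for lists, 585 kept the call and 163 lost it. With the filter at the 50th percentile Nr3c1 is not tested. Signals near background limit what can be seen, since the added constant of 32 shrinks changes there.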

Other observations

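Clock and growth hormone genes belong to lists that did not pass against control, and the members given here were chosen after their values were seen. In the long course Dbp, a clock output regulator, was -1.77 ± 0.32 at 24 h (limma adjusted p = 0.00103) and -1.57 ± 0.32 at 72 h (adjusted p = 0.00121), both against the controls with 4 arrays each. Nr1d2 was -1.94 ± 0.35 at 18 h of the short course (adjusted p = 0.00235, 3 arrays) and -1.42 ± 0.29 at 24 h of the long course (adjusted p = 0.00425, 4 arrays). The labels give no time of day.

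Igfbp2, a carrier of insulin-like growth factors, was -3.93 ± 0.49 at 168 h of the long course, and Serpina6 was -4.32 ± 0.46. Ghr was -1.53 ± 0.29 at 12 h of the short course (adjusted p = 0.00522, 2 arrays), and Igfals -1.51 ± 0.31 at 8 h (adjusted p = 0.00222, 3 arrays). Obp3 signal was 1478 ± 1069 (SD, n = 4) in the short-course controls and 194.8 ± 228.6 (n = 3) at 48 h, but 421.9 ± 490.4 (n = 4) in the long-course controls and 3379 ± 931 (n = 4) at 96 h.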
